A study of Rattus norvegicus with 34 samples.

How the data were processed

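The livers' RNA was prepared with TriReagent and a column cleanup and measured on Affymetrix rat genome arrays, per the labels. The deposited values are linear probe set intensity values, and the authors' processing notes name MAS5 and RMA without a version, a role or an order. Within a strain the sorted signals of the arrays had a coefficient of variation of 1.62% in Brown Norway and 1.47% in F344 rats, so the arrays of a strain had been brought to a near common distribution before deposit. Median signals differed between the strains, so tests were run within each strain, and the strains were compared by their effects of age alone.

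The table has 24946 probe sets, of which 23324 have values in each strain and 21702 in both, and 53 are array controls. A single gene symbol is given for 17584, several for 393 and none for 6916. Of the annotated Entrez identifiers 54 are not in the reference, which was used for names alone, without coordinates. Each gene was represented by the probe set with the highest mean log2 signal over the strain's arrays. This gave 11984 genes in Brown Norway and 11943 in F344 rats. Per-sample columns not used here numbered 0.

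Signals under 32 were set to 32, since low linear signals spread widely on a log scale, and log2 was taken. A gene was tested if it lay above that floor on at least 3 Brown Norway or 4 F344 arrays, a minimum chosen after the data had been seen, which left 8584 and 9206 genes. Of these, 7956 had the same probe set in both strains. Effects were estimated with limma 3.58.1 in R 4.3.3, with a mean per group within the strain and moderated variances, and p-values were adjusted by the method of Benjamini and Hochberg. A gene passed at an adjusted p under 0.05. The p-values rest on the arrays of separate animals. The difference between the strains' effects was tested from the separate estimates with their standard errors. Where arrays of the lower group lay at the floor, the fold is a lower bound and is written as at least that size. Signals are means with SD over animals, and log2 fold changes come from floored values.

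Lists of genes, 43 in number, were fixed before the data were examined, from general knowledge of rat liver, and a list was tested if at least 3 members were. They were tested with limma's camera with a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals. Members were also counted after adjusting over the list alone.

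The genes named in the text were chosen by a rule fixed before the data were examined. It took up to 8 genes with the largest changes in each direction among those that passed and whose groups did not overlap, up to 4 members of smallest p from each list, the 5 genes of smallest p where fewer than 10 passed, and a fixed set of drug-metabolising and ageing genes. Other genes, among them Por, Ephx1 and Cyp3a23-3a1 under toluene, the clock genes, and the members of shared sets, were chosen after their values were seen.

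Simulated data had 100 genes changed by 1 and 100 by 2 on the log2 scale, with noise drawn independently for each gene. The change of 1 was recovered in 67% and of 2 in 87% of genes for Brown Norway rats of 24 against 4 months. For F344 rats of 24 against 6 months the shares were 75% and 86%. Many changed genes ease the adjusted threshold, so these shares may be too high for comparisons in which few genes passed. The false share of calls was 1.72% to 7.78% over the comparisons.

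The alternatives took each probe set on its own, the mean of a gene's probe sets, the genes above the median of mean signal, another quantile or median scaling, floors of 8 and of 4 times the floor used, a variance trend with robust moderation, array quality weights, a 2-fold minimum, the compared groups alone, and each array left out in turn. Another 4 were added after the data had been seen: the GAPDH ratio as a covariate, leaving out the 5 F344 arrays with a ratio above 2.5, leaving out replicate 3 of the 12-month dosed rats, and dosed in place of control rats for old age in Brown Norway rats. Where arrays are compared in splits, each split of the same arrays into groups of the same sizes was counted once, up to 100 splits.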

Results

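Gene expression was measured in the livers of 34 male rats of 2 inbred strains, with a separate microarray for each animal. The Brown Norway rats, which were housed individually, were 4, 12 or 24 months old. At each age 3 of them received the solvent toluene in corn oil by gavage at 1 g/kg and were killed 4 h later. Another 3 served as controls, whose labels give no treatment. The F344 rats were 6, 11, 18 or 24 months old, with 4 animals at each age and no dosing, and they came from their supplier 1 week before necropsy. The study concerns the enzymes and transporters that metabolise foreign compounds in ageing male rats. Median probe set signal per array was 35.6 to 38.3 in Brown Norway and 44.9 to 47.1 in F344 rats, and 52.8% to 54.8% and 59.5% to 61.1% of probe sets lay above the floor of 32. The ratio of the 3' to the 5' probe sets of GAPDH, a sign of RNA integrity, was 0.774 to 0.944 in Brown Norway rats. In F344 rats it ranged from 1.31 to 7.33, with group means of 2.72 ± 1.22 (SD, n = 4) at 6 months, 3.61 ± 2.67 at 11, 2.54 ± 1.86 at 18 and 1.81 ± 0.33 at 24 months. The number of arrays limits the precision of every value that follows.

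The comparison of F344 rats of 24 and 6 months asked how the liver differs in old age. Genes with a male pattern of expression fell together. Hsd3b5, a male-specific steroid dehydrogenase, had a signal of 2584 ± 370 (SD, n = 4) at 6 months and 43.3 ± 24.1 at 24 months, at least 56.1-fold lower (log2 fold change -5.81, SE 0.29, adjusted p = 5.82e-09). Cyp2c11, the main male-specific cytochrome P450 of rat liver, fell from 5855 ± 299 to 316 ± 191 (SD, n = 4), 21.7-fold (log2 fold change -4.44, SE 0.32, adjusted p = 1.85e-07). The estrogen sulfotransferase Sult1e1 was 25.8-fold, Obp3, a carrier protein of male urine, 24.3-fold, and Cyp3a2 21.4-fold lower. Of the 12 measured genes of the male-dominant list, 12 fell, with a median log2 fold change of -3.92, and 12 passed when adjusted over the list alone. The list test gave an adjusted p of 1.2e-26 with a preset and 0.0161 with an estimated correlation between genes.

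Genes with a female pattern moved the other way. Cyp2c12, the female-specific P450 that hydroxylates steroid sulfates, rose from 332 ± 79.1 to 6437 ± 783 (SD, n = 4), 19.7-fold (log2 fold change 4.30, SE 0.56, adjusted p = 0.000206). The aldo-keto reductase Akr1b7 was below the floor on the 4 arrays of 6 months and reached 2183 ± 775 at 24 months, at least 65.0-fold higher. A1bg was at least 36.9-fold higher, with a wide spread at 24 months (1695 ± 1414, SD, n = 4). The prolactin receptor Prlr was 15.5-fold and the transcriptional cofactor Trim24 15.2-fold higher, and Cux2, a female-specific transcription factor of the liver, was at least 4.32-fold higher. Of 10 measured genes of the female-dominant list 7 rose and 1, Fmo1, fell (log2 fold change -1.16, SE 0.31, adjusted p = 0.0326), with the same counts of 7 and 1 adjusted over the list alone. Cyp2c7 (0.12) and Cyp3a9 (-0.04) had log2 fold changes near 0. The median was at least 2.09, since Cux2 and Sult2a2, the members next to it, were at the floor on the 4 arrays of 6 months. The list passed with an adjusted p of 2.44e-09, and 0.0161 with an estimated correlation.

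**Figure D1:**
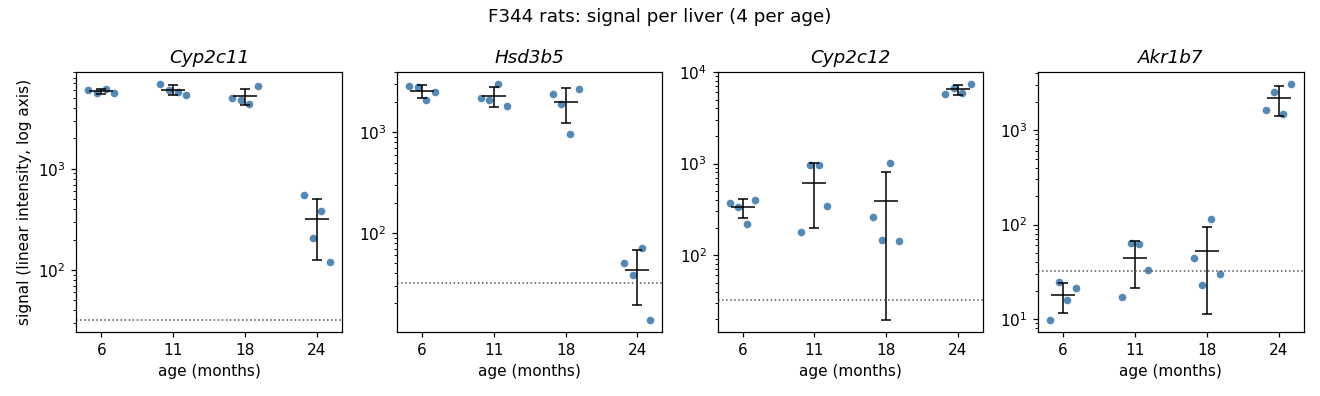
Signal (linear intensity on a log axis) of 2 male-pattern genes (Cyp2c11, Hsd3b5) and of Cyp2c12 and Akr1b7 in F344 livers against age in months, with a point per rat, the mean as a horizontal bar, the SD as error bars (shortened at the lower end where the SD comes near the mean) and the floor of 32 dotted. Mean Cyp2c11 signal was 5193 at 18 months and 316 at 24 months, and mean Cyp2c12 signal was 391 and 6437.

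Among 172 measured genes of xenobiotic metabolism, 34 fell and 13 rose between 6 and 24 months in F344 rats, and 42 fell and 15 rose when adjusted over the list alone. These 172 include members of the male- and female-dominant lists, such as Cyp2c11, Cyp3a2, Sult1e1 and Cyp2c12. The counts are therefore not independent of those lists. The transporters fell as a group: 6 of 26 were lower and 0 higher, with the same counts adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.000218, and 0.0295 with an estimated correlation). They included Slc22a8, which takes organic anions into cells and was below the floor on the 4 arrays of 24 months (at least 13.7-fold lower, adjusted p = 0.000387). The bile acid and drug importer Slco1b2 was 1.63-fold lower. Abcc9 (3.40-fold lower) entered the list by its gene family name and is not known as a drug or bile acid transporter. Of 34 cytochromes P450, 11 fell and 3 rose (adjusted over the list alone 15 and 3), and this list passed with the preset correlation (adjusted p = 2.89e-05) but had an adjusted p of 0.106 with an estimated correlation. Of 50 conjugating enzymes 8 fell and 6 rose (adjusted over the list alone 12 and 6, adjusted p = 0.0301, and 0.422 with an estimated correlation), and of 62 other phase 1 enzymes 9 fell and 4 rose (adjusted over the list alone 10 and 6), with no call of that list (adjusted p = 0.118). Besides the male-pattern genes, the methyltransferase Inmt was 14.3-fold lower and Akr1c3 at least 8.18-fold lower. Among the genes that rose were the steroid sulfotransferases Sult2a6 (6.81-fold, log2 fold change 2.77, SE 0.50, adjusted p = 0.00292) and Sult2a2 (at least 4.21-fold) and the glutathione transferase Gstp1, a marker of preneoplastic foci (142 ± 14.1 to 387 ± 146, SD, n = 4, 2.61-fold, adjusted p = 0.007). Rgn, also known as senescence marker protein, was 1.35-fold lower (adjusted p = 0.0127).

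Some genes of immune cells were also higher in F344 rats of 24 than of 6 months. Of 22 interferon-responsive genes 7 rose (adjusted over the list alone 10 rose and 1 fell), among them the transcription factor Irf1 (1.96-fold, adjusted p = 0.00219), and the list held with an estimated correlation (adjusted p = 7.65e-05, and 0.0176 with an estimated correlation). Of 16 macrophage genes 7 rose (adjusted over the list alone 15), such as Cd68 (179 ± 29.5 to 342 ± 54.6, SD, n = 4, 1.91-fold) and the Fc receptor chain Fcer1g (1.91-fold). Of 9 genes of MHC class II antigen presentation 6 rose (adjusted over the list alone 8), such as RT1-DMa (at least 2.13-fold). Both lists passed with the preset correlation (adjusted p = 1.84e-09 and 1.59e-07) and each had an adjusted p of 0.106 with an estimated correlation. Of 10 genes of natural killer and cytotoxic cells 3 rose (adjusted over the list alone 8, adjusted p = 2.84e-05, and 0.108 with an estimated correlation), including the protease Gzmk (at least 2.00-fold) and the receptor Klrd1 (at least 1.52-fold), both below the floor on 3 of 4 arrays of 6 months.

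In sum 681 of 9206 genes passed in F344 rats between 6 and 24 months, 408 higher and 273 lower. At least 2-fold changes were seen in 206 of them. The count fell to 392 without replicate 1 of 24 months, to 444 without replicate 3 of 6 months and to 407 without the 5 arrays whose GAPDH ratio was above 2.5, of which 2 belonged to 6 months. With array quality weights it was 1153. Without those 5 arrays Elovl6, an enzyme of fatty acid elongation that was 11.0-fold higher (72 ± 42.7 to 1028 ± 999, SD, n = 4), Sult2a2 and Rgn lost their calls (adjusted p = 0.0522, 0.0717 and 0.0515), and Abcc9 and Nr1d1 lost their calls with a 4-fold higher floor (adjusted p = 0.203 and 0.436). Slco1b2 lost its call with the mean of a gene's probe sets (adjusted p = 0.124) and Rgn with quantile scaling again (0.0528). Of 15 clock genes 2 fell, both of them repressors, Nr1d1 (at least 3.70-fold) and Nr1d2 (2.39-fold), and the list was not called (adjusted p = 0.2).

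The step from 18 to 24 months in F344 rats asked when these differences arose. Cyp2c11 fell from 5193 ± 960 to 316 ± 191 (SD, n = 4), 19-fold (log2 fold change -4.25, SE 0.32, adjusted p = 4.27e-07), Cyp3a2 22.0-fold and Hsd3b5 at least 40.7-fold. Cyp2c12 rose 23.5-fold, from 391 ± 419 to 6437 ± 783, Akr1b7 from 52.6 ± 41.4, with 2 of 4 arrays below the floor, to 2183 ± 775 (SD, n = 4), and A1bg at least 35.5-fold. Of 12 male-dominant genes 11 fell (adjusted over the list alone 12), with a median log2 fold change of -3.11, and of 10 female-dominant genes 5 rose (adjusted over the list alone 6 rose and 1 fell). Both lists held with an estimated correlation (adjusted p = 6.52e-36 and 5.4e-13, and 0.00416 for each with an estimated correlation). The mean of the male-dominant genes on single arrays lay 0.00 to 0.55 below that of 6 months at 18 months, and 2.41 to 3.95 below it at 24 months. Of 172 genes of xenobiotic metabolism 15 fell and 4 rose (adjusted over the list alone 29 and 10), among them Cyp3a18 (3426 ± 431 to 1193 ± 440, log2 fold change -1.58). Of the 34 cytochromes P450, 6 fell and 1 rose (adjusted over the list alone 10 and 1, adjusted p = 2.71e-06, and 0.151 with an estimated correlation).

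Other genes moved between 18 and 24 months as well. Of 15 clock genes 4 fell and 2 rose (adjusted over the list alone 6 and 4): Nr1d1 (at least 5.33-fold), Nr1d2 (3.40-fold), Tef (2.15-fold) and Dbp (at least 3.16-fold) were lower, and the list had no shift one way (adjusted p = 0.137). The time of day at which the livers were taken is not given in the labels, so this shift stands beside each group of genes in this comparison. The metal-binding Mt2A was 4.88-fold lower. Of 18 genes of fatty acid synthesis 3 rose (adjusted over the list alone 7, adjusted p = 1.52e-05, and 0.425 with an estimated correlation), such as Elovl6 (at least 12.5-fold). In all 162 genes passed, 81 higher and 81 lower, and 73 changed at least 2-fold. The count was 249 without replicate 3 of 24 months and fell to 69, 79 and 86 without its replicates 2, 1 and 4, and to 85, 84 and 100 without replicates 1, 3 and 4 of 18 months. It was 93 without the arrays of high GAPDH ratio, where Elovl6 lost its call, as it did with only these 2 groups in the fit (adjusted p up to 0.0693).

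**Figure D2:**
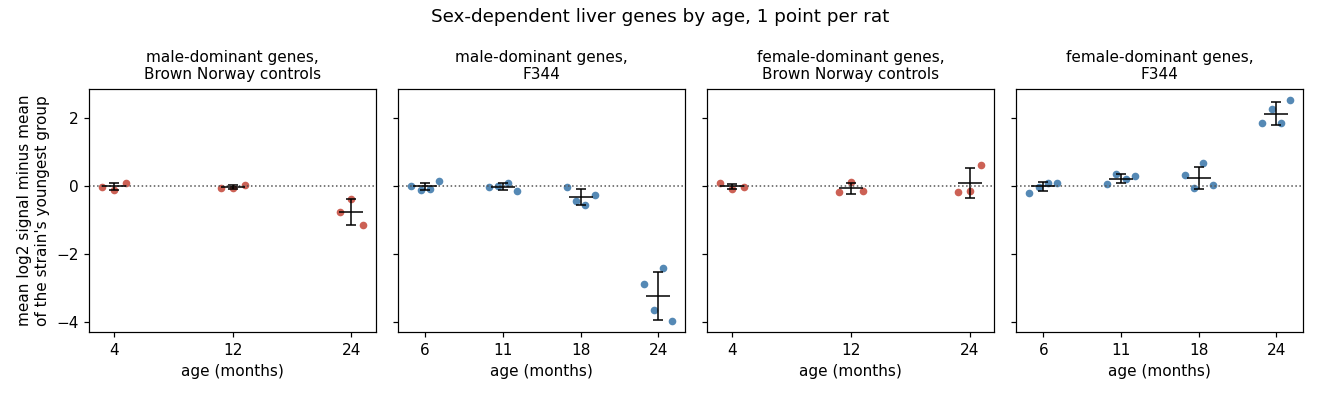
Mean log2 signal of the male-dominant (12 genes) and female-dominant (7 genes measured in Brown Norway, 10 in F344) lists on each array, minus the mean of the strain's youngest group, against age in months in Brown Norway controls (n = 3 per age) and F344 rats (n = 4 per age), with means and SD. The 4 F344 rats of 24 months lay at -2.41 to -3.95 in the male-dominant list and the 3 Brown Norway controls of 24 months at -0.38 to -1.13.

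Immune and acute-phase genes were among those that differed between F344 livers of 18 and 6 months. The calcium-binding S100a9 of neutrophils and monocytes rose from 55.9 ± 7.56 to 250 ± 95.0 (SD, n = 4), 4.25-fold (log2 fold change 2.09, SE 0.27, adjusted p = 0.00194). The ubiquitin ligase Neurl3 rose 3.55-fold, the endotoxin-binding Lbp 3.79-fold (471 ± 96.4 to 1905 ± 830), and S100a11 3.69-fold. Of 9 MHC class II genes 6 rose (adjusted over the list alone 8), with a median log2 fold change of 1.46, such as RT1-Da (347 ± 45.0 to 1196 ± 310, SD, n = 4, 3.37-fold, adjusted p = 0.011) and RT1-Bb (3.18-fold). Of 16 macrophage genes 4 rose (adjusted over the list alone 14), such as Fcer1g (1.93-fold). These lists passed with the preset correlation (adjusted p = 8.12e-14 and 5.9e-13) and each had an adjusted p of 0.0635 with an estimated correlation. Of 22 interferon-responsive genes 3 rose (adjusted over the list alone 8), and this list held (adjusted p = 3.7e-06, and 0.0166 with an estimated correlation). Of 21 acute-phase genes 2 rose (adjusted over the list alone 3, adjusted p = 3.7e-06, and 0.108 with an estimated correlation). Prlr was already 5.36-fold higher at 18 months (61.0 ± 29.0 to 318 ± 111).

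Of the 172 genes of xenobiotic metabolism 6 passed at 18 months in F344 rats, 2 higher and 4 lower, with the same counts adjusted over the list alone. The fatty acid hydroxylase Cyp4a8 (164 ± 60.6 to 560 ± 153, SD, n = 4, 3.56-fold, adjusted p = 0.011) and the flavin monooxygenase Fmo5 (732 ± 296 to 1818 ± 160, 2.63-fold, adjusted p = 0.0041) rose, and Inmt (3.97-fold), Dhrs7l1 (2.80-fold), Abcc9 (2.04-fold) and Akr1c3 (2.02-fold) fell. Abcc9 is in that list by its gene family name alone. Outside that list the elastase Cela1 was at least 5.04-fold and the histidine-degrading Hal 2.07-fold lower. In all 99 of 9206 genes passed, 84 higher and 15 lower, and 45 changed at least 2-fold. The count was 206 without replicate 4 of 18 months, whose GAPDH ratio was 5.31, and 427 with array quality weights, and it fell to 22 and 51 without replicates 3 and 2 of 18 months and to 38, 28 and 47 without replicates 1, 2 and 3 of 6 months. It was 37 without the 5 arrays of high GAPDH ratio, with 0 genes of xenobiotic metabolism. Those numbered 1 without replicate 3 of 18 months and 3 without replicate 2 of 18 or replicate 1, 2 or 3 of 6 months.

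Most genes named for 18 against 6 months lost their calls under some alternatives: Dhrs7l1 under 13 of 20 (adjusted p up to 0.185), Akr1c3 under 11 of 19 (0.321), both with quantile scaling again, Hal under 8 (0.0946) and Inmt under 6 of 20 (0.181). Abcc9 lost its call under 5 of 19 (0.402). Prlr (0.0706) and RT1-Bb (0.062) lost theirs under 3 of 20 and RT1-Da and Cyp4a8 (0.0575 each) under 2. Without replicate 3 of 18 months these 9 genes lost their calls. Without replicate 2 of 6 months Dhrs7l1, Akr1c3, Hal, Inmt, Prlr, RT1-Bb and RT1-Da did, and without its replicate 1 Dhrs7l1, Akr1c3, Hal, Abcc9 and Prlr. Dhrs7l1, Hal and Inmt did without replicate 2 of 18 or replicate 3 or 4 of 6 months, and Akr1c3 in the first 2 of these cases. The genes of xenobiotic metabolism, Hal, RT1-Bb, Fcer1g (0.0512) and Cela1 lost theirs without the arrays of high GAPDH ratio, and Cela1 (adjusted p up to 0.21), S100a9 (0.0904) and Neurl3 (0.464) with a 4-fold higher floor. Lbp and S100a11 passed under 20 of 20.

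At 11 months 0 genes passed against 6 months in limma, with 357 at an unadjusted p under 0.05. The 5 genes of smallest p were Cdkn1a, a cell cycle inhibitor (206 ± 32.3 and 500 ± 155, SD, n = 4, log2 fold change 1.24, SE 0.27), Dapk1 (0.60, SE 0.13), Tpd52l1 (1.03, SE 0.24), Sh3bp2 (-0.55, SE 0.13) and the glutathione transferase Gsta3 (111 ± 65.2 and 284 ± 70.0, log2 fold change 1.52, SE 0.36), each with an adjusted p of 0.718. Genes induced by glucocorticoids and fasting passed as a list in camera: 19 of 20 had negative log2 fold changes, with a median of -0.26 and 0 genes passing adjusted over the list alone (adjusted p = 3.6e-05, and 0.0108 with an estimated correlation). In fry 0 of 40 lists passed in this comparison, so this list did not pass there. Of 172 genes of xenobiotic metabolism 0 passed in limma over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. The 11-month group held 2 of the 5 arrays with a GAPDH ratio above 2.5, and without those 5 arrays 0 genes passed as well.

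In Brown Norway controls the comparison of 24 with 4 months asked the same question of old age. Some genes of plasma cells, macrophages and the interferon response were higher. The immunoglobulin gene Ighl2 rose from 82.9 ± 19.8 to 415 ± 112 (SD, n = 3), 4.99-fold (log2 fold change 2.32, SE 0.36, adjusted p = 0.0146), and Jchain, which links immunoglobulins, rose 2.69-fold. Of the 3 measured markers of B and plasma cells 1 rose (adjusted over the list alone 2, adjusted p = 0.00216, and 0.153 with an estimated correlation). Glipr1 rose at least 3.26-fold (33.5 ± 3.66 to 115 ± 36.4, adjusted p = 0.00792), Lgals3bp 2.83-fold and Isg15, a ubiquitin-like protein induced by interferon, 1.98-fold (51.5 ± 4.31 to 102 ± 1.22, adjusted p = 0.00815). Of 21 interferon-responsive genes 2 rose, Isg15 and Ifi27 (adjusted over the list alone 10), and this list held with an estimated correlation (adjusted p = 5.64e-11, and 0.00916 with an estimated correlation). Of 16 macrophage genes 2 rose, the complement gene C1qb (207 ± 24.2 to 647 ± 228, 3.02-fold) and the scavenger receptor Cd163 (2.5-fold), and 14 passed adjusted over the list alone. The macrophage list had a median log2 fold change of 1.27 and passed with the preset correlation (adjusted p = 2.97e-16, and 0.153 with an estimated correlation). In the dosed rats of the same ages its median was 0.13. The genes named here lost their calls without replicate 3 of the 4-month controls and with only these 6 arrays in the fit. Ighl2, Jchain, C1qb and Cd163 also did in the dosed rats. Ighl2, Ifi27, C1qb and Cd163 did without replicate 1 of the 24-month controls, and Jchain, Ifi27, C1qb and Cd163 without replicate 1 of the 4-month controls. C1qb and Cd163 did without replicate 2 of the latter as well. The adjusted p rose up to 1 for C1qb and Cd163, 0.674 for Jchain, 0.47 for Ifi27, 0.458 for Lgals3bp, 0.344 for Ighl2, 0.28 for Glipr1 and 0.267 for Isg15. In the dosed rats Glipr1, Lgals3bp, Isg15 and Ifi27 passed. Of 8 MHC class II genes 0 passed over all genes in limma and 5 adjusted over the list alone, with a median log2 fold change of 1.35 (adjusted p = 3.74e-07, and 0.289 with an estimated correlation). Replicate 1 of the 24-month controls lay 1.78 log2 units above the 4-month controls in the mean of the macrophage genes and 3.03 in that of the MHC class II genes, and the other 24-month controls 0.64 and 0.75, and 0.51 each.

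Of 165 measured genes of xenobiotic metabolism 2 fell in Brown Norway rats of 24 months and 7 adjusted over the list alone. Cyp3a9 fell from 2487 ± 268 to 815 ± 349 (SD, n = 3), 3.22-fold (log2 fold change -1.68, SE 0.28, adjusted p = 0.0238), and the glutathione transferase Gstm7 from 706 ± 114 to 245 ± 124, 3.11-fold (adjusted p = 0.0391). Of 32 cytochromes P450, 27 had negative log2 fold changes, and adjusted over the list alone 10 were lower and 1 higher (adjusted p = 2.17e-06, and 0.209 with an estimated correlation). Cyp2c11 had a signal of 4920 ± 164 at 4 months and 2983 ± 1154 at 24 months (log2 fold change -0.79, SE 0.24, adjusted p = 0.176), and the aryl hydrocarbon receptor target Cyp1a2 had 4196 ± 550 and 2646 ± 530 (log2 fold change -0.68, SE 0.17, adjusted p = 0.102). The 12 male-dominant genes had negative log2 fold changes with a median of -0.53, of which 0 passed over all genes in limma and 4 adjusted over the list alone (adjusted p = 8.78e-06, and 0.289 with an estimated correlation). A low mean of this list was not confined to 24 months: replicate 3 of the 12-month dosed rats lay at -1.16 on the log2 scale, below the controls (-0.38 to -1.13) and the dosed rats (-0.31 to -0.52) of 24 months. Outside these lists the amino acid enzymes Gls2 (2.41-fold) and Gnmt (1.97-fold, log2 fold change -0.98, SE 0.18) fell. These 2, Cyp3a9 and Gstm7 lost their calls without any 1 of the 4-month controls, without replicate 1 of the 24-month controls and in the dosed rats, and Gls2, Gnmt and Gstm7 without replicate 3 of the 24-month controls (adjusted p up to 0.47 for Cyp3a9 and 1 for the others). In all 21 of 8584 genes passed, 15 higher and 6 lower, with 1000 at an unadjusted p under 0.05. The count was 137 and 49 without replicates 2 and 3 of the 24-month controls and 6 without their replicate 1, and 7, 12 and 0 without replicates 1, 2 and 3 of the 4-month controls, and it was 0 with only these 6 arrays in the fit. It was 79 without replicate 3 of the 12-month dosed rats, an array left out after its values were seen. The genes of xenobiotic metabolism numbered 5 without replicate 2 of the 24-month controls, 6 without that 12-month array, and 0 without their replicate 1, without any 1 of the 4-month controls, and in the dosed rats of the same ages.

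At 12 months 0 genes passed against 4 months in Brown Norway rats in limma, with 335 at an unadjusted p under 0.05. The genes of smallest p included Ncald (163 ± 50.6 and 50.3 ± 1.85, SD, n = 3, log2 fold change -1.65, SE 0.29, adjusted p = 0.211), the DNase gene Dnase2b (116 ± 19.2 and 555 ± 68.8, log2 fold change 2.27, SE 0.43, adjusted p = 0.256) and Ifi27 (log2 fold change 0.56, SE 0.12, adjusted p = 0.569). The count was 2 without replicate 2 of the 4-month controls and 1 without replicate 3 of the 12-month controls. Between 12 and 24 months 2 genes rose, Lgals3bp (61.2 ± 2.12 to 162 ± 50.7, SD, n = 3, 2.57-fold, adjusted p = 0.0289) and N4bp2l1, which was below the floor in the 12-month controls (at least 1.70-fold higher, adjusted p = 0.015). Glipr1 (log2 fold change 1.32, SE 0.22) and Isg15 (0.84, SE 0.14) each had an adjusted p of 0.0511. Of the genes of xenobiotic metabolism 0 passed in either comparison in limma, with 3 at an unadjusted p under 0.05 between 4 and 12 months, and adjusted over the list alone 0 passed between 4 and 12 months and 13 between 12 and 24 months, 11 lower and 2 higher. The count between 12 and 24 months was 48 and 28 without replicates 2 and 3 of the 24-month controls, 71 without replicate 3 of the 12-month dosed rats, and 0 without replicate 1 or 2 of the 12-month controls. Lgals3bp also lost its call without replicate 3 of those or replicate 1 of the 24-month controls, and both genes with a floor of 8 (adjusted p up to 0.331 each).

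**Figure D3:**
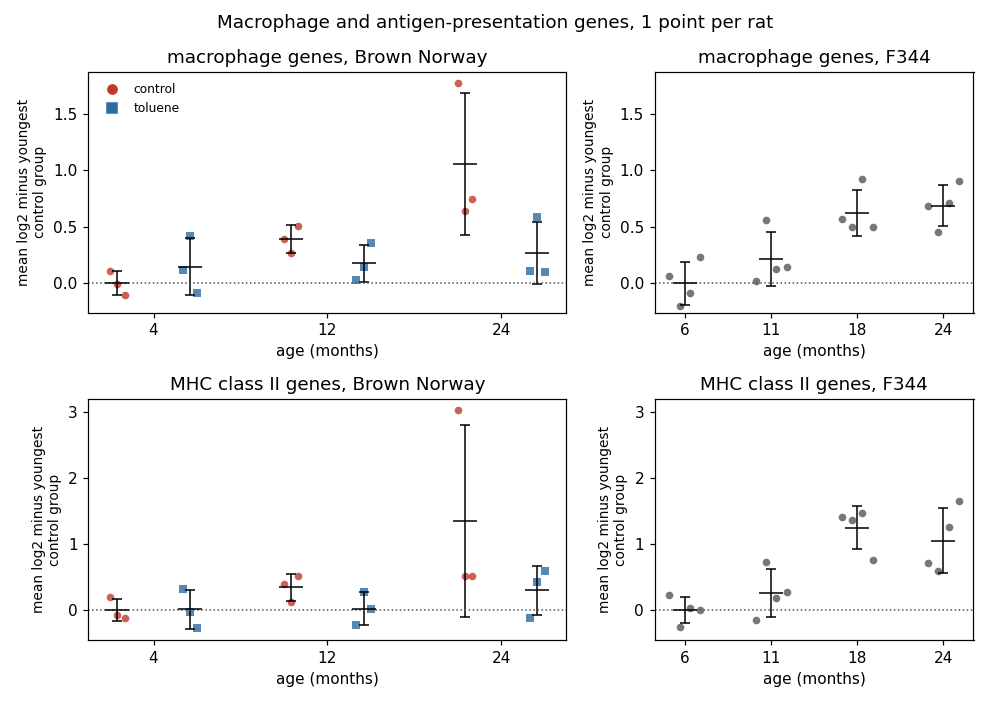
Mean log2 signal of the macrophage and MHC class II genes on each array, minus the mean of the strain's youngest control group, against age in months in Brown Norway rats (n = 3 per group; circles for controls, squares for toluene) and F344 rats (n = 4 per age), with means and SD. Brown Norway controls of 24 months lay at 0.64, 0.75 and 1.78 in the macrophage genes and dosed rats of that age at 0.10, 0.11 and 0.59.

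The ageing effects of the 2 strains were set against each other for the 7956 genes measured with the same probe set in both. The strains differ in housing, supplier, young age and scaling as well, so the difference is between the 2 sets of animals. In 38 genes the effect of old age (24 against 4 months in Brown Norway, 24 against 6 in F344) differed. Hsd3b5 fell by 5.81 on the log2 scale in F344 rats, and the Brown Norway effect was higher by 5.27 (SE 0.38, adjusted p = 5.44e-11). Cyp2c11 changed by -0.79 in Brown Norway and -4.44 in F344 rats (difference 3.65, SE 0.40, adjusted p = 7.28e-07), and Cyp2c12 by 0.41 and 4.30 (difference -3.89, SE 0.65, adjusted p = 0.00204). Sult1e1 (4.62), Cyp3a2 (3.89), Serpinb9b (-3.52), Rtn4 (-3.04) and Trim24 (-2.80) also differed. The differences for Hsd3b5, Cyp2c12, Serpinb9b and Trim24 have no exact size, since some of their arrays were at the floor. Hsd3b5, Sult1e1, Cyp2c11 and Cyp3a2 passed under 25 of 25 alternatives, and Trim24 lost its call under 5 of 23 (adjusted p up to 0.364), and Cyp2c12, Serpinb9b and Rtn4 each under 1 of 23 (0.0641, 0.0694 and 0.0784). Of the 158 shared genes of xenobiotic metabolism 8 differed, and 18 adjusted over the list alone. Without replicate 1 of the 4-month Brown Norway controls 25 genes differed, without replicate 2 of the F344 rats of 24 months 24, and without replicate 3 of the 24-month Brown Norway controls 58.

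Some genes of old age were shared. Of 14 genes higher in Brown Norway and 354 higher in F344 rats 5 were the same (Glipr1, Isg15, Lgals3bp, Ms4a6bl1 and Plek), where chance gives 0.623 (Fisher's exact test, p = 0.000243), and of 6 and 255 lower genes 2 were the same, Gnmt and Gstm7, where chance gives 0.192 (Fisher's exact test, p = 0.0141). Genes are not independent of each other, as this test assumes, so its p-values may be too small. With an unadjusted p under 0.01, 87 higher and 32 lower genes were shared, where chance gives 13 and 6.04. The shared higher genes then included the macrophage genes C1qa, C1qb, Cd68 and Csf1r, and the shared lower genes included Cyp2c11, Cyp2a2, Cyp1a2 and Inmt. Across genes, which are not independent replicates, the effects correlated with Pearson's r of 0.442 and Spearman's rho of 0.368, and 110 of 158 genes of xenobiotic metabolism had the same sign. The shared count of 7 became 64 and 14 without replicates 2 and 3 of the 24-month Brown Norway controls, 4 without their replicate 1, 4, 3 and 0 without replicates 1, 2 and 3 of the 4-month controls, and 4 without replicate 2 or 4 of the F344 rats of 6 months. The shared lower genes numbered 13 without replicate 2 of the 24-month Brown Norway controls. They numbered 0 without replicate 1 or 3 of those or without any 1 of the 4-month controls.

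Toluene was given to Brown Norway rats to see whether the liver's response to a foreign compound depends on age. The controls received no treatment per the labels, so each effect named for toluene includes those of gavage and corn oil. At 4 months Alas1, the rate-limiting enzyme of heme synthesis, rose from 681 ± 57.5 to 2491 ± 75.3 (SD, n = 3), 3.67-fold (log2 fold change 1.87, SE 0.25, adjusted p = 0.00774). Tsku, a secreted protein of the liver, was below the floor in the 3 controls and reached 333 ± 63.3, at least 10.3-fold higher (adjusted p = 0.00774). At 12 months both rose again, Alas1 from 754 ± 139 to 2752 ± 118 (SD, n = 3), 3.69-fold (adjusted p = 0.00548), and Tsku from 25.8 ± 8.33, with 2 of 3 controls below the floor, to 581 ± 430, at least 15.1-fold (adjusted p = 0.00225). The nuclear receptor Nr0b2, which represses bile acid synthesis, also rose, from 50.4 ± 10.6 to 392 ± 142 (7.57-fold, adjusted p = 0.037). In all 2 genes passed at 4 and 3 at 12 months, with 271 and 396 at an unadjusted p under 0.05. Alas1 and Tsku were the shared genes, where chance gives 0.000699 (Fisher's exact test, p = 8.14e-08). That p may be too small, since the test takes genes as independent and both comparisons use the same estimate of each gene's variance. They belong to a list of 17 targets of the drug-sensing receptors CAR and PXR, of which 17 at 4 and 14 at 12 months had positive log2 fold changes, with 2 passing at each age over all genes and adjusted over the list alone. That list passed with the preset correlation at both ages (adjusted p = 9.63e-07 and 1.89e-07, and 0.136 and 0.0979 with an estimated correlation). Other members had values such as log2 fold changes of 1.04 at 4 and 0.77 at 12 months for Por, the electron donor of the cytochromes P450, and 0.35 and 0.53 for Ephx1.

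At 4 months 0 genes passed, in limma, without replicate 2 or 3 of the controls or replicate 1 or 3 of the dosed rats (271 genes at an unadjusted p under 0.05 with all arrays), so that Alas1 and Tsku lost their calls (adjusted p up to 0.0803 for Alas1), and 4 passed without replicate 1 of the controls. At 12 months 1 gene passed without replicate 2 of the controls or of the dosed rats, where Alas1 lost its call, and Nr0b2 lost its call without any 1 of the 6 arrays (adjusted p up to 0.282), while 0 passed with only these 6 arrays in the fit. With a 4-fold higher floor Tsku lost its calls at both ages (adjusted p = 0.97 at 4 months).

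At 24 months the genes that passed were others. With an unadjusted p under 0.01, 4 and 24 months shared 5 higher genes and 12 and 24 months shared 3. Chance gives 0.492 and 0.554 if genes are independent. Alas1, Cers6 and Meox2 were in both sets. Of lower genes 1 and 0 were shared. Scd, the stearoyl-CoA desaturase, was below the floor in the 3 controls and reached 539 ± 325 (SD, n = 3) after toluene, at least 15.0-fold higher (adjusted p = 5.58e-05). The ceramide synthase Cers6 rose from 125 ± 17.5 to 273 ± 23.4 (2.20-fold, adjusted p = 0.0222), Cep152 rose at least 2.22-fold, Phf19 was at least 1.70-fold higher and N4bp2l1 at least 1.70-fold lower. N4bp2l1 was below the floor in the dosed rats. Its fall therefore rests on the same 24-month controls (54.4 ± 4.08, SD, n = 3) as its rise from 12 months. Alas1 had a signal of 533 ± 216 in controls and 928 ± 197 after toluene (log2 fold change 0.87, SE 0.25, adjusted p = 0.284), and Tsku 156 ± 77.0 and 115 ± 51.2 (-0.37, SE 0.45, adjusted p = 0.808). Of 17 CAR and PXR targets 0 passed over all genes in limma and 1 adjusted over the list alone, 8 had positive log2 fold changes, and the list was not called (adjusted p = 0.799). The list names 24 genes, of which these 17 were tested. Probe sets assigned to several genes cannot enter it, so its result does not cover them. The 16 macrophage genes had negative log2 fold changes with a median of -0.88, of which 0 passed over all genes and 13 were lower adjusted over the list alone (adjusted p = 4.1e-11, and 0.464 with an estimated correlation). The 24-month controls are the arrays on which these genes were high. Of 29 PPARalpha targets, genes of fatty acid oxidation, 0 passed over all genes and 10 were lower adjusted over the list alone (adjusted p = 1.51e-07, and 0.464 with an estimated correlation). In all 5 genes passed, with 953 at an unadjusted p under 0.05. The count was 48 and 15 without replicates 2 and 3 of the controls, 3 without their replicate 1, 1 without replicate 1 of the dosed rats, 10 without replicate 3 of the 12-month dosed rats, and 0 with only these 6 arrays in the fit. Cers6 lost its call without replicate 1 of the controls or without any 1 of the dosed rats (adjusted p up to 0.267 over the alternatives). Without replicate 1 of the dosed rats N4bp2l1, Phf19 and Cep152 also lost theirs. Phf19 did so without replicate 2 of the dosed rats, and Cep152 without their replicate 3 or replicate 1 of the controls. These 3 and Cers6 lost their calls with a floor of 8 (adjusted p up to 0.391, 0.372 and 0.277 over the alternatives for the 3).

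**Figure D4:**
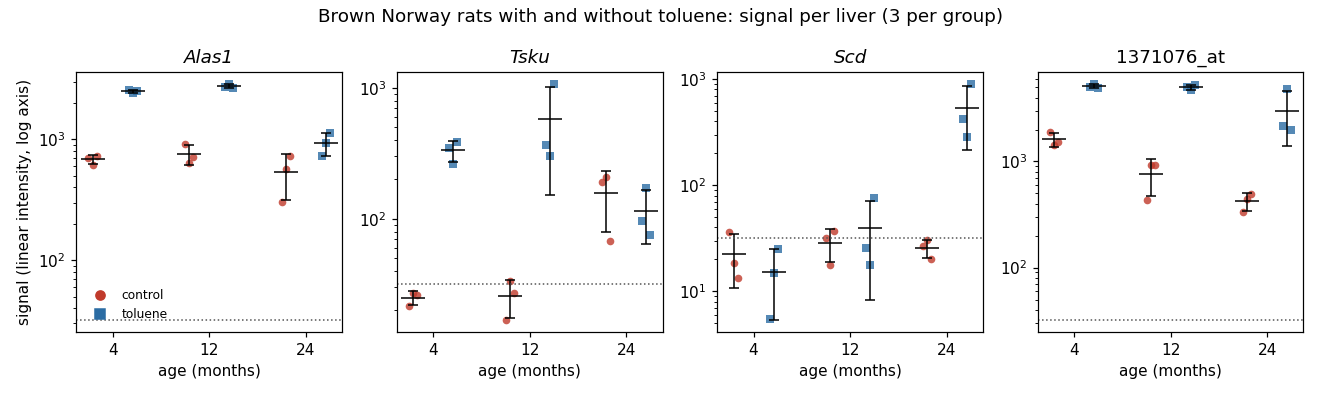
Signal (linear intensity on a log axis) of Alas1, Tsku, Scd and a probe set assigned to several genes (shown under its identifier) in Brown Norway livers against age in months, with a point per rat (circles for controls, squares for toluene), the mean as a horizontal bar, the SD as error bars (shortened at the lower end where the SD comes near the mean) and the floor of 32 dotted. Mean Alas1 signal after toluene was 2491 at 4, 2752 at 12 and 928 at 24 months, and that of Scd at 24 months was 539.

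Averaged over the 3 ages, 6 genes rose with toluene: Alas1 (2.91-fold, log2 fold change 1.54, SE 0.14, adjusted p = 0.000115), Tsku (adjusted p = 0.000901, with no exact size, since 5 of 9 controls were below the floor), Cers6 (1.67-fold, adjusted p = 0.00681), Scd (adjusted p = 0.00681, with no exact size, since 7 of 9 controls and 5 of 6 dosed rats of 4 and 12 months were below the floor), the aryl hydrocarbon receptor Ahr (1.69-fold, adjusted p = 0.0291) and the homeobox gene Meox2 (at least 2.43-fold, adjusted p = 0.0298). Of the CAR and PXR targets 2 rose (adjusted over the list alone 3, adjusted p = 7.45e-08, and 0.0819 with an estimated correlation). Whether the effect depended on age was tested directly. The effect at 24 minus that at 4 months differed in 1 gene, Scd (adjusted p = 0.00449). Its log2 difference of 3.96 (1.90 to 4.77 over the alternatives) has no exact size, since the 24-month controls and 5 of the 6 arrays of 4 months lay below the floor. For Tsku, which was below the floor in the 4-month controls, it was -3.73 (-4.25 to -1.65 over the alternatives, adjusted p = 0.0834) and for Alas1 -1.0 (SE 0.35, adjusted p = 0.967). Over the 3 ages together the effect differed in 3 genes, Scd (adjusted p = 0.0061), Tsku and N4bp2l1 (adjusted p = 0.0398 each). Scd lost its calls averaged, between 24 and 4 months and over the ages with a floor of 8 and with a 4-fold higher floor (adjusted p up to 0.434, 0.548 and 0.314). Over the ages Tsku lost its call under 16 of 27 alternatives (adjusted p 0.00888 to 0.477) and N4bp2l1 under 19 of 25, both scalings among them (0.0151 to 0.784), and averaged Ahr lost its call under 16 of 27 (0.000883 to 0.283) and Tsku with a 4-fold higher floor (0.112). The difference between 24 and 4 months had 2 genes without replicate 3 of the 24-month controls and 5 without replicate 3 of the 12-month dosed rats. Over the 3 ages 1 gene differed without any 1 of 11 arrays: replicates 1, 2 and 3 of the 4-month controls, 2 and 3 of the 4-month dosed, 1 and 2 of the 12-month controls, 1 and 2 of the 24-month controls and 1 and 3 of the 24-month dosed rats.

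Of the 165 genes of xenobiotic metabolism 0 passed after toluene at any age in limma, over all genes or adjusted over the list alone. At 4, 12 and 24 months 5, 13 and 34 of them had an unadjusted p under 0.05. Probe sets assigned to several genes cannot enter the 165, so these counts do not cover them. The counts therefore do not show that no enzyme of xenobiotic metabolism responded to toluene. Averaged over the ages 0 passed as well, and 15 had an unadjusted p under 0.05. Cyp2e1, the P450 best known for oxidising small solvents, had log2 fold changes of 0.07, 0.01 and -0.05 at 4, 12 and 24 months, Cyp1a2 had -0.13, 0.15 and 0.12, and Cyp3a23-3a1 had 0.16, 0.21 and 0.31. Their adjusted p was at least 0.446. On simulated data a log2 change of 1 was recovered in 71% of 100 genes at 4 months, 60% at 12 and 68% at 24 months. Far more genes were changed there than passed after toluene, which eases the adjusted threshold. The share recovered in the real data may therefore be lower. Outside the genes with a single name, a probe set assigned to several genes had 761 ± 285 in controls and 4988 ± 223 (SD, n = 3) after toluene at 12 months (6.95-fold, adjusted p = 0.00201 among probe sets), and 422 ± 81.4 and 2981 ± 1596 at 24 months (6.56-fold, adjusted p = 0.00203). At 4 months it had 1614 ± 252 and 5132 ± 247 (log2 fold change 1.68, SE 0.31, adjusted p = 0.153). Averaged over the ages it was 5.26-fold higher after toluene in limma (adjusted p = 1.33e-05 among probe sets). In controls it was 3.84-fold lower at 24 than at 4 months (log2 fold change -1.94, SE 0.31, adjusted p = 0.0124 among probe sets). Cyp1a1 was not analysed here.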

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

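The test for a mislabelled array and the tests with the GAPDH ratio, with dosed rats or without the array highest in natural killer genes were chosen after the results were seen. Chance flags about 1 in 20 groups: of 280 groups of 4 arrays examined for an array far from the others, 31 had one, where chance gives 14. The floor adds to this: in 6 of the 31 the other 3 arrays lay at the floor, which fixes the measure at 1. Of 245 groups with no array at the floor 20 had one, where chance gives 12.2. The measure is Dixon's ratio, the gap to the nearest array over the range of the group, set against its 95% limit for 4 arrays.

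Highest and lowest are meant within the 4 arrays of the same age. Among array measures, replicate 4 of the F344 rats of 18 months had the highest GAPDH ratio (Dixon's ratio 0.8572) and actin ratio (0.9189) and the lowest mean of the MHC class II genes (0.8476). Replicate 4 of 24 months had the lowest median signal (0.8715), and replicate 3 of 6 months the highest mean of the clock genes (0.9587). At 24 months, replicate 4 stood apart in Prlr (0.845), Nr1d1 (0.8684) and Nr1d2 (0.8943), where it was highest, and in Obp3 (0.8341) and Tef (0.8354), where it was lowest, and replicate 1 in Rtn4 (0.9035) and replicate 3 in Klrd1 (0.8584), both lowest. At 18 months, replicate 3 was highest in A1bg (1) and Cux2 (1) and lowest in Cyp3a2 (0.9389). Replicate 2 was lowest in Hal (0.872) and replicate 1 highest in Cyp3a18 (0.925). At 11 months, replicate 3 was highest in Poteml2 (0.9039) and A1bg (0.8877), replicate 2 in Cd68 (0.9018), Cux2 (1) and Klrd1 (1), replicate 1 in Slco1b2 (0.884) and replicate 4 in Dbp (0.9501). At 6 months, replicate 1 was lowest in RT1-DMa (0.838) and Serpinb9b (0.8723) and highest in Gzmk (1). Replicate 3 was lowest in Slc22a8 (0.983) and highest in Slco1b2 (0.8415), and replicate 4 highest in Gstp1 (0.8814) and Klrd1 (1).

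The effect of old age differed between the strains in 38 genes, as log2 difference in Hsd3b5 (5.274), Sult1e1 (4.622), Cdh17 (4.253), Cyp3a2 (3.893), Cyp2c11 (3.65), Cyp2c12 (-3.89), Serpinb9b (-3.518), Elovl6 (-3.265), Rtn4 (-3.041) and Trim24 (-2.8). Cdh17 passed at an adjusted p of 0.049 and lost its call under 15 of 24 alternatives, and Elovl6 under 8 of 23. The effect of toluene differed with age in Scd (3.964 between 24 and 4 months, from values mostly at the floor) and, over the 3 ages, in Tsku and N4bp2l1 (adjusted p = 0.03975 each), which lost these calls under 16 of 27 and 19 of 25 alternatives. A probe set assigned to several genes, which the gene comparisons leave out, had a log2 fold change of 2.396 with toluene averaged over the ages.

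The loss of male and gain of female liver expression in F344 rats of 24 months was weighed against 3 technical explanations. RNA degradation is argued against, since 12 of 12 male-dominant genes still passed with the GAPDH ratio as a covariate. Without the 5 arrays of high GAPDH ratio 10 of 12 passed. Their median log2 fold change was then -3.91, against -3.92 with all arrays. RNA of female rats is argued against by the 2 Y-linked genes Uty and Eif2s3y, which were above the floor on each 24-month array. A single mislabelled array is argued against because 4 of 4 arrays of 24 months lay below each 6-month array. Age stays open as an explanation, with the supplier's conditions and the time of day, which were not tested.

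The macrophage genes that were high in Brown Norway controls of 24 months and lower after toluene share the same 3 control arrays. In dosed rats the median change between 4 and 24 months was 0.1004 of that in controls, which cannot be told apart from an action of toluene on these genes, since the design gives no other 24-month control arrays. A lower share of hepatocytes would raise the markers of other cell types alike. The macrophage and endothelial genes had medians of 1.27 and 0.126 (permutation test over genes, p = 7e-05). That test takes genes as replicates and holds no spread between animals, so its p decides nothing here. On the 3 control arrays the macrophage means were 0.64 to 1.78 and the endothelial means 0.11 to 0.27 above 4 months. These values argue against a lower share of hepatocytes as the whole cause, on 3 arrays alone.

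The natural killer and cytotoxic genes that rose in F344 rats of 24 months may come from a large granular lymphocyte leukaemia in 1 rat, a known disease of this strain. The highest of the 24-month arrays had a Dixon's ratio of 0.5025, under the limit, and 3 of 4 lay above each 6-month array. That array as the whole cause is argued against, since without it the mean of the list was still higher by a log2 value of 0.48 (SE 0.146, 95% interval 0.157 to 0.802, and 0.692 with it). A leukaemia as part of the increase stays open, as do age and disease in more than 1 rat, which were not tested.

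Splits of the same arrays show how often chance gives as many genes that passed. In F344 rats, 1 of 35 splits, the real one, gave as many genes at 18 against 6 months (99, highest other 28), 24 against 6 (681, highest other 2) and 24 against 18 (162, highest other 37). This is the smallest share that 35 splits can give, and it makes chance unlikely for these counts. For 11 against 6 months the real count was 0, which 35 of 35 splits reach whatever they give (highest other 1), so the splits show nothing there. For toluene averaged over the ages 1 of 100 splits reached the real 6 genes (highest other 3), which makes chance unlikely for this count. For the effect over the 3 ages 1 of 100 reached 3 (highest other 1). These splits swap dosed and control rats within each age, so they mimic no effect of toluene at any age. They cannot decide whether the effect differs with age. The splits for the effect at 24 minus 4 months have the same limit. Of these, 12 of 100 reached the real 1 (highest other 3), and chance is not excluded. For the difference between the strains 10 of 100 reached the real 38. These splits swap ages within each strain, so they mimic no effect of age in either strain and not an equal effect in both. They cannot decide whether the effects differ, and chance is not excluded by them. The highest other split gave 234, and the reason for it was not tested.

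The Brown Norway comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. For 12 against 4 months the real count was 0, which 10 of 10 reach whatever they give (highest other 0). For 24 against 12 months 1 of 10 gave the real 2 (highest other 1). For toluene 1 of 10 gave the real 2 at 4 months (highest other 0), 3 at 12 months (highest other 0) and 5 at 24 months (highest other 2). For 24 against 4 months 2 of 10 gave at least the real 21. The other one called 175 genes, with replicates 1 and 2 of 24 months and replicate 2 of 4 months on 1 side, and the reason for it was not tested.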

How the results depend on the processing

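The 4 tests with the GAPDH ratio as a covariate, without the arrays of high GAPDH ratio, without a 12-month dosed array and with dosed rats were chosen after the data had been seen. No paired analysis was possible because the labels share no pairing between groups. Over the alternatives the named genes' results were the same in 2262 cases, lost their call in 360, gained one in 26 and reversed in 0. List results were the same in 182 cases, lost their call in 214 and reversed in 0. Scaling by quantiles again or by medians moved no count by more than 1.5 times. Quantile scaling again gave 2 higher and 2 lower genes of xenobiotic metabolism in F344 rats of 18 against 6 months, in place of 2 and 4, and 6 higher and 1 lower gene shared by the strains, in place of 5 and 2. Unless a reason is given, the cause was not tested.

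With each probe set on its own the counts were 43 for Brown Norway 24 against 4 months, 4 for 24 against 12, 5 for toluene at 12 months, 12 averaged, 1 across the 3 ages and 15 for the overlap of the strains. The mean of a gene's probe sets gave 5 for 24 against 12 months and 2 for the toluene effect at 24 minus 4 months. Genes above the median of mean signal, where fewer genes were tested, gave 13 for Brown Norway 24 against 4 months, 0 for 24 against 12, 1 for toluene at 24 months, 0 for the effect at 24 minus 4 and 1 across the ages, 97 for F344 24 against 18 months, 24 for the strain difference and 4 for the overlap. A variance trend with robust moderation gave 40, 5 and 2 for Brown Norway 24 against 4, 24 against 12 and the effect at 24 minus 4 months, and 15 for the overlap.

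Array quality weights gave, in Brown Norway rats, 5 for 12 against 4 and 30 for 24 against 12 months, 6 and 8 for toluene at 4 and 24 months, 10 averaged and 3 for the effect at 24 minus 4. In F344 rats they gave 427 for 18 against 6, 1153 for 24 against 6 and 629 for 24 against 18 months, with 41 genes of xenobiotic metabolism in the last, and 14 for the overlap.

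A floor of 8 gave 0 for Brown Norway 24 against 12 months, 1 for toluene at 24 months, 0 for the effect at 24 minus 4 and 0 across the ages, 85 for F344 24 against 18 months, 22 for the strain difference and 3 for the overlap. A floor 4 times that used gave 6 for Brown Norway 24 against 4 months (1 of xenobiotic metabolism), 0 for 24 against 12, 2 for toluene at 24 months, 0 and 0 for the difference by age, 55 for F344 18 against 6 months and 1 for the overlap. Fewer genes lie above the higher floor. These counts of 0 are from limma, where the comparisons had 1249 (24 against 12 months), 420 (24 minus 4) and 581 (3 ages) genes at an unadjusted p under 0.05 with the floor used.

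A 2-fold minimum, which can only lower counts, gave 13 for Brown Norway 24 against 4 months, 1 for 24 against 12, 3 for toluene at 24 months, 45, 206 and 73 for F344 18 against 6, 24 against 6 and 24 against 18 months, and 2 for the overlap. The overlap was 119 at an unadjusted p under 0.01 and 38 at an adjusted p under 0.1. With only the compared groups in the fit, where fewer arrays estimate the variance, Brown Norway 24 against 4 months gave 0 (0 of xenobiotic metabolism), 24 against 12 months 0, and toluene at 12 and 24 months 0 and 0. F344 rats gave 54 for 18 against 6 (3 of xenobiotic metabolism) and 65 for 24 against 18 months (10), the strain difference 19 and the overlap 0.

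The GAPDH ratio as a covariate gave 192 for F344 18 against 6 and 252 for 24 against 18 months. Without the arrays of high GAPDH ratio, with fewer samples, the counts were 37 for 18 against 6 (0 of xenobiotic metabolism), 407 for 24 against 6 and 93 for 24 against 18 months. Without replicate 3 of the 12-month dosed rats they were 79 for Brown Norway 24 against 4 months (6 of xenobiotic metabolism), 71 for 24 against 12, 10 for toluene at 24 months and 5 for the effect at 24 minus 4. With dosed rats in place of controls, 0 genes of xenobiotic metabolism passed between 4 and 24 months.

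With each array left out in turn the lowest and highest counts in Brown Norway rats were 0 and 2 for 12 against 4 months, 0 and 137 for 24 against 4 (xenobiotic metabolism 0 and 5), 0 and 48 for 24 against 12, 0 and 4 for toluene at 4 months, 1 and 3 at 12, 1 and 48 at 24, 4 and 9 averaged, 1 and 2 for the effect at 24 minus 4 and 1 and 4 across the ages. In F344 rats they were 0 and 0 for 11 against 6 months, 22 and 206 for 18 against 6 (xenobiotic metabolism 1 and 7), 392 and 644 for 24 against 6 (36 and 52) and 69 and 249 for 24 against 18 (14 and 26). The strain difference had 24 and 58 and the overlap 0 and 64. Signal over background limits the genes seen, since 52.8% to 54.8% of probe sets in Brown Norway and 59.5% to 61.1% in F344 rats lay above the floor.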

Other observations

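The dosed Brown Norway rats can be compared by age as well, a comparison chosen after the data had been seen. Between 4 and 24 months 23 genes passed, 19 higher and 4 lower. Of 21 interferon-responsive genes 8 rose and 12 adjusted over the list alone, with a median log2 fold change of 0.67, and the list held (adjusted p = 1.11e-26, and 0.000117 with an estimated correlation). Of 17 targets of CAR and PXR 16 had negative log2 fold changes, with a median of -0.36, 1 fell and 4 adjusted over the list alone (adjusted p = 1.69e-08, and 0.0351 with an estimated correlation).

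In F344 rats of 24 against 6 months, some genes of cholesterol synthesis were higher. Of 20 such genes 4 rose (adjusted over the list alone 9), such as Sqle (153 ± 27.2 to 377 ± 48.2, SD, n = 4, 2.48-fold, adjusted p = 0.00219). The list passed with the preset correlation (adjusted p = 9.82e-05) but had an adjusted p of 0.14 with an estimated correlation. Across genes, which are not independent replicates, the effects of toluene at 4 and 12 months had a Pearson's r of 0.0939, those at 4 and 24 months 0.225, and those at 12 and 24 months -0.294.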
